A study of Mus musculus with 16 samples.

How the data were processed

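Single-nucleus RNA sequencing was done on lumbar spinal cord of C57BL/6 mice in 16 libraries made with the 10x Genomics nuclei isolation kit and the 3ʹ v3.1 reagents. Some mice had experimental autoimmune encephalomyelitis (EAE), a T cell driven model of multiple sclerosis in which immune cells enter the spinal cord and damage myelin. Some were given an inhibitor of BTK (Bruton's tyrosine kinase), a kinase that signals downstream of the B cell receptor and of Fc receptors in B cells, microglia and other myeloid cells. The labels name neither the compound nor its dose or schedule. The groups held 4 vehicle naive, 3 BTK inhibitor (BTKi) naive, 4 vehicle EAE and 5 BTKi EAE libraries. The labels number the samples within a group and do not state that each is a separate animal, so the library was the replicate. The p-values for single genes and for shares of nuclei measure the spread between these libraries.

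The deposited files hold, for each library, raw UMI counts per gene and barcode, the barcodes that the authors' cell calling kept, and the names of 32285 genes. According to the submitters' processing notes the reads were counted with Cell Ranger 7.1.0 against mm10; the annotation release and the count settings were not stated, and nothing was normalized. The files hold 343491 barcodes and 321223008 UMIs. Vehicle naive 1 and 2, BTKi naive 1, vehicle EAE 4 and BTKi EAE 4 each hold over 30000 barcodes. Gene positions were read from GENCODE vM21, an annotation of the same build that was not taken from the authors.

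A barcode was kept with at least 1000 UMIs and 500 genes and at most 5% mitochondrial UMIs, among the 10000 deepest barcodes of its library. The highest Scrublet scores of each library, computed in scanpy 1.11.5, were then removed at 0.8% of nuclei per 1000 nuclei kept, 1750 nuclei in all, against 112 at the caller's own thresholds. This left 54961 nuclei, 1561 to 4978 per library, with a median of 1395 to 2952 UMIs per nucleus. Counts were normalized to 10000 per nucleus and log-transformed. Leiden clustering at resolution 1.0 (igraph 0.11.9) used 3000 variable genes, 30 principal components and 15 neighbours. Clusters that held several types were clustered again with 1500 genes, 15 components and resolution 0.5.

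Clusters were named from marker genes fixed before the data were examined, by at least 3 markers at 2 times their level elsewhere and at least 20 counts scaled to library size (CPM), or 1.4 times within a parent cluster. Neuron clusters needed 3 neuronal markers at 0.5 times their level in all nuclei or more, and a cluster mixed with or led by markers of another class stayed unnamed; immune classes, vessel and fibroblast classes, and OPC with committed OPC did not count as other classes to each other. Names end in "-like" because no label gives a cell type. The second clustering, the final naming rule and its limit of 30% free RNA for neuron clusters were set after cluster markers and cluster sizes per group had been seen and before any test between groups. Unnamed clusters were left out. They took up 28.6% of the vehicle naive nuclei, 16.8% of BTKi naive, 15.3% of vehicle EAE and 13.8% of BTKi EAE. The largest unnamed cluster, led by Prph, Slc5a7 and Nefh of motor neurons, held 3438, 1582, 509 and 651 nuclei in that order. Another unnamed cluster of 2333 nuclei, led by the immune transcripts Tyrobp, C1qb and Fcer1g beside neuronal ones, held 76, 52, 1297 and 908.

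Free RNA was estimated from the shallowest 25% of barcodes of each library. Its share in a class was the median, over neuron transcripts (oligodendrocyte transcripts for neuron-like nuclei), of the class's CPM over the CPM of those barcodes. This measure counts true expression and mixed droplets as free RNA too.

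UMI counts were summed per library and class for classes with at least 20 nuclei. The quasi-likelihood test of edgeR 4.0.16 with trimmed-mean normalization and its expression filter compared groups in a single fit per class, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were vehicle EAE against vehicle naive, BTKi EAE against vehicle EAE, BTKi naive against vehicle naive, and the interaction of treatment and disease. Values per library are CPM on the normalized library sizes, and log2 changes are the fitted ones. Of 200 genes given simulated changes in these libraries 67 had a 2-fold change, and in the disease comparison 61.2% of these 67 were recovered in oligodendrocyte-like, 50.7% in OPC-like, 47.8% in astrocyte-like, 79.1% in neuron-like and 1.49% in microglia-like nuclei. For BTKi EAE against vehicle EAE the recovery at 2-fold was 68.7%, 49.2%, 41.8%, 71.6% and 49.2%, and at 1.5-fold it was between 8.96% and 52.2%.

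The 28 gene lists were fixed before the data were examined and tested with limma camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a class and comparison. A result given for a list is the preset one unless stated. The endothelial activation and blood-brain barrier lists could not be tested because the endothelial-like class had under 20 nuclei in most libraries. No cluster was named B/plasma-like or neutrophil-like, and monocyte/macrophage-like nuclei reached 20 in only 2 BTKi EAE libraries, so they had no gene test. MHC class II and proliferation were not tested in OPC-like nuclei, with 1 measured member each.

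Shares of named nuclei were compared by two-sided exact permutation of libraries, adjusted over classes. The smallest p that 4 against 4 or 3 against 4 libraries can give is 0.0286, and 5 against 4 can give 0.00794. Correlations across genes between the disease and the treatment changes were set beside 20 simulations with no effect on the same shared vehicle EAE libraries, and beside values with vehicle EAE parted in 2 sets of 2 libraries.

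Named genes were chosen by a rule fixed in advance. In each class they were up to 3 with the largest rise and 3 with the largest fall among genes past the threshold with a mean of at least 10 CPM in a group and no overlap between the groups, leaving out fixed markers, mitochondrial genes and unnamed models. Up to 4 members with the smallest p were taken from each described list, and Btk in every class. With fewer than 6 passing genes, all past the threshold were named. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio stands with its 95% counting interval (exact binomial), which covers counting error only.

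Replicate numbers were checked as pairs by the correlation of residual expression between libraries with the same number. For vehicle naive and BTKi naive every pair passed 0.1 in the 3 deepest classes, with values of 0.10 to 0.34 in astrocyte-like, 0.16 to 0.29 in neuron-like and 0.11 to 0.36 in oligodendrocyte-like nuclei, so the naive comparison was also read from a fit with the number as a block. That block entered the single fit of all groups. Same-numbered EAE libraries therefore also shaped its estimates, and it is not a test of the naive pairs alone. In each other pairing of groups some value lay below 0.1.

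Alternatives fixed in advance were median-ratio size factors, DESeq2 1.42.0, no expression filter, at least 1000 genes per nucleus, no barcode limit, doublets kept, Leiden resolution 0.5, leaving out the 5 libraries over 30000 barcodes, the library set as a term (libraries numbered 1 to 8 against 9 to 16 in the file names, which sets numbers 1 and 2 of each group against the rest), the replicate block, each library left out in turn, and an estimated correlation. Those chosen after seeing the data were a mitochondrial limit of 20%, free RNA subtracted, at least 10 nuclei per library and unnamed clusters counted in their closest class. The others were leaving out a cholinergic cluster from the neuron-like nuclei of the main naming and, for the lists and correlations, leaving out vehicle EAE 4. The largest unnamed cluster stayed in the count of unnamed clusters. A grouping by mitochondrial RNA was also set after the data were seen. In vehicle naive 1, vehicle EAE 4 and BTKi EAE 3, 4 and 5, over 30% of barcodes past the UMI and gene minima failed the mitochondrial limit (38.7%, 52.6%, 39.9%, 57.8% and 57.3%), against at most 24.4% elsewhere. These 5 mitochondria-rich libraries were fitted as a term and left out. Analyses ran in Python 3.11.15 and R 4.3.3.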

Results

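Nuclei of lumbar spinal cord were profiled in 4 vehicle naive, 3 BTKi naive, 4 vehicle EAE and 5 BTKi EAE libraries, to compare EAE with no disease and a BTK inhibitor with vehicle. Total UMIs were 45637177, 22636193, 11268311 and 14447702 in vehicle naive 1 to 4, and 37998390, 16055337 and 15124502 in BTKi naive 1 to 3. Vehicle EAE 1 to 4 held 14387130, 8374638, 8657154 and 40491720, and BTKi EAE 1 to 5 held 10007658, 11367861, 13903370, 37892283 and 12973582. Named nuclei numbered 10089, 11149, 11520 and 11915 in the 4 groups in this order. Neuron-like nuclei numbered 4474, 6913, 4440 and 5691, oligodendrocyte-like nuclei 3880, 3013, 4528 and 4343, and astrocyte-like nuclei 1278, 908, 685 and 617. Oligodendrocyte precursor (OPC)-like nuclei numbered 208, 215, 297 and 264, and microglia-like nuclei 66, 10, 784 and 437. Vehicle EAE 4 gave 448 of the 685 vehicle EAE astrocyte-like nuclei, and the library with the fewest gave 27. The clusters differed in share between groups within several classes. Of the vehicle naive oligodendrocyte-like nuclei, 2399 lay in a cluster led by Carns1, Anln and Klk6, and 2418 of the vehicle EAE ones in a cluster led by Ptgds and Il33. Of the microglia-like nuclei, 48 of 66 vehicle naive ones lay in a cluster led by Cd84, Fyb and Ptprc, and 422 of 784 vehicle EAE ones in a cluster led by Ly86 and Ifi204. Of the OPC-like nuclei, 66 of 208 vehicle naive and 9 of 297 vehicle EAE ones lay in a cluster with Gpr17 among its leading genes beside Vcan and Pdgfra.

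The cell make-up of the cord was compared first. Microglia-like nuclei, the resident macrophages of the cord, made up 7.22% ± 2.78 (SD, n = 4) of named nuclei in vehicle EAE and 0.694% ± 0.552 (n = 4) in vehicle naive libraries. Monocyte/macrophage-like nuclei made up 2.90% ± 1.99 against 0.0136% ± 0.0272, T/NK-like nuclei 0.793% ± 0.562 against 0, and dendritic-like nuclei 0.722% ± 0.391 against 0. A count of 0 among 10089 named nuclei allows a share of up to 0.0297% at 95% by counting error alone, in pooled nuclei. Committed OPC-like nuclei, which express Bmp4 and Enpp6, made up 2.13% ± 0.594 against 0.183% ± 0.0821. They form a cluster of 276 nuclei led by Tcf7l2 and one of 257 led by Gpr17 and Bmp4 with OPC markers Sox6, Vcan and Tnr. Counting the OPC-like cluster with Gpr17 (66 vehicle naive and 9 vehicle EAE nuclei) here would narrow this gap. In each of these 5 classes, and in the peripheral immune classes together (4.41% ± 2.87 against 0.0136%), every vehicle EAE library lay above every vehicle naive library, with the smallest exact permutation p the design allows, 0.0286, and an adjusted p of 0.0619, which misses the threshold. Astrocyte-like nuclei made up 5.50% ± 5.06 against 12.96% ± 3.02 (exact permutation p = 0.0857, adjusted p = 0.159; without vehicle EAE 4 the mean was 3.09%, every library lay below the naive ones, and adjusted p was 0.0531), and neuron-like nuclei 38.0% ± 9.65 against 44.1% ± 8.86 (exact permutation p = 0.457, adjusted p = 0.540). The other classes had adjusted p between 0.186 and 0.80. The nuclei left unnamed, including the cluster led by Tyrobp, C1qb and Fcer1g with 76 vehicle naive and 1297 vehicle EAE nuclei, are not in these shares. Nor is the largest unnamed cluster, closest to neuron-like nuclei (3438 and 509), so the neuron-like difference stays open.

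With the BTK inhibitor in EAE the immune shares were lower on average, and none of the differences passed the test. Monocyte/macrophage-like nuclei made up 0.956% ± 0.856 (SD, n = 5) in BTKi EAE and 2.90% ± 1.99 (n = 4) in vehicle EAE (exact permutation p = 0.0873), or 0.590% without BTKi EAE 2 (p = 0.0286, adjusted p = 0.279). Dendritic-like nuclei made up 0.322% ± 0.159 against 0.722% ± 0.391, microglia-like nuclei 4.28% ± 2.46 against 7.22% ± 2.78, and the peripheral immune classes together 1.68% ± 1.14 against 4.41% ± 2.87 (exact permutation p = 0.0556, 0.127 and 0.103). Each of these had an adjusted p of 0.351. Committed OPC-like nuclei made up 2.00% ± 0.823 against 2.13% ± 0.594 (exact permutation p = 0.810, adjusted p = 0.954). In naive mice, neuron-like nuclei made up 61.9% ± 2.47 (n = 3) with the inhibitor and 44.1% ± 8.86 (n = 4) without (exact permutation p = 0.0571, adjusted p = 0.371), or 68.2% and 58.7% with unnamed clusters counted in their closest class (p = 0.286), and no class passed the test. In pairs of the same number neuron-like nuclei made up 60.43%, 60.44% and 64.7% with the inhibitor and 47.3%, 55.1% and 38.4% without; these 3 paired swaps cannot give a p under 0.25.

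**Figure D1:**
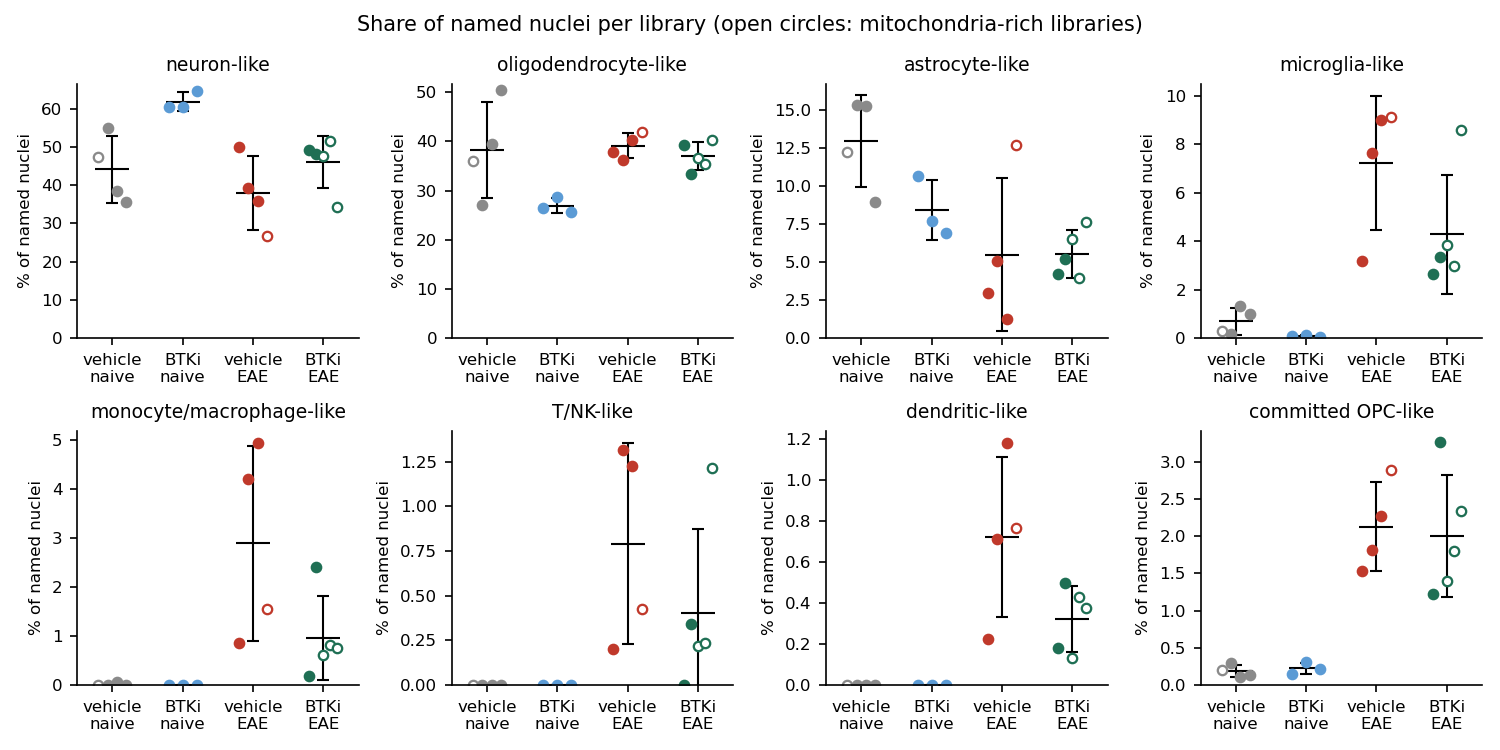
Percent of named nuclei (vertical axis) in each library for 8 classes, by group, with the group mean and SD as a black bar; open circles are the 5 mitochondria-rich libraries. Microglia-like nuclei take up 7.22% in vehicle EAE, 4.28% in BTKi EAE and 0.694% in vehicle naive libraries on average.

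Vehicle EAE was compared with vehicle naive to show what disease changed in each class without drug. In oligodendrocyte-like nuclei, the myelin-forming cells, genes of antigen presentation and of the interferon response rose and genes of cholesterol synthesis fell. H2-D1, an MHC class I heavy chain (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499 in mm10), had 491 ± 112 CPM (SD, n = 4) in vehicle EAE against 21.9 ± 3.17 (n = 4), a log2 change of 4.49 (SE 0.22, edgeR adjusted p = 4.63e-12). C4b, a complement component, had 397 ± 103 CPM against 29.8 ± 9.57. Hmgcs1, an early enzyme of cholesterol synthesis (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), had 149 ± 29.0 CPM against 397 ± 51.7, a log2 change of -1.41 (adjusted p = 0.00018). In all, edgeR called 341 genes higher and 144 lower of 11827 tested.

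Of the interferon-stimulated genes, 35 of 37 measured members rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 change of 3.51 (camera adjusted p = 5.86e-49). Members with the smallest p included Irf7 (log2 change 4.25), a regulator of the interferon response, and Ifit1 (5.19), an effector. MHC class I presentation had 14 of 19 higher and 0 lower (15 and 0 adjusted over the list alone, median 2.45, adjusted p = 3.36e-22), with B2m at 3.91 and H2-K1 at 4.10. All 5 measured MHC class II genes rose, also adjusted over the list alone (median 5.56, adjusted p = 1.03e-05, and 0.11 with an estimated correlation). Complement had 6 of 12 higher (8 higher and 1 lower adjusted over the list alone, median 2.48, adjusted p = 1.61e-08), C1qa at 3.44 among them. The disease-associated oligodendrocyte list had 7 of 16 higher and 0 lower (7 and 1 adjusted over the list alone, median 0.63, adjusted p = 1.35e-06), led by the serine protease inhibitor Serpina3n at 3.65, with Il33 at 0.87 and Cd63 at 1.20. Cholesterol synthesis had 15 of 24 lower and 0 higher (18 lower adjusted over the list alone, median -0.78, adjusted p = 6.40e-19), with Fdft1 at -1.22 and Idi1 at -1.15. Oxidative phosphorylation had 4 of 23 lower (18 adjusted over the list alone, median -0.69, adjusted p = 7.97e-14, and 0.13 with an estimated correlation). In the myelin list 1 of 23 rose, Tspan2 at 0.58 (4 adjusted over the list alone, median 0.12, adjusted p = 0.00527, and 0.43 with an estimated correlation). Proliferation (adjusted p = 0.883), glucocorticoid response (0.845, with 3 members higher and 2 lower) and immediate early and heat shock genes (0.790) did not pass. The largest rises by the naming rule were Lcn2, an iron-carrier-binding protein (at least 64.0-fold higher), Cst7, a cystatin (at least 50.2-fold), and Cd74, the MHC class II chaperone, with a ratio of 331 and a 95% exact binomial counting interval of 91.3 to 2735. The largest falls were Hsd11b1 (-1.95), Ntng1 (-1.75) and Etnppl (-1.73).

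Markers of other cells moved too. Immune transcripts in oligodendrocyte-like nuclei rose with a median of 3.19 (13 of 16 members, 15 adjusted over the list alone, adjusted p = 1.96e-19), and neuron transcripts fell with a median of -0.86 (0 of 12 over all genes and 8 adjusted over the list alone, adjusted p = 1.24e-06, and adjusted p = 0.18 with an estimated correlation). Mitochondrial transcripts had a median of -0.46 (adjusted p = 0.000105, and 0.28 with an estimated correlation), and ribosomal proteins did not pass (adjusted p = 0.301). The estimated share of free RNA was 22.8% in vehicle EAE and 35.4% in vehicle naive libraries. After its subtraction 81 genes were higher and 34 lower, the interferon, MHC class I, disease-associated and cholesterol lists kept their calls, and MHC class II (adjusted p = 0.49), complement (0.70) and immune transcripts (0.98) did not. The count was 602 higher and 801 lower with mitochondria-rich libraries as a term, 448 and 732 without them, and 754 and 1072 without vehicle EAE 4 alone, where ribosomal proteins fell (adjusted p = 8.2e-05). The total was 284 without vehicle naive 1, 306 without vehicle naive 2, 308 without vehicle EAE 2 and 280 without vehicle EAE 3.

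In astrocyte-like nuclei reactive, interferon and MHC genes rose, and cholesterol synthesis fell. Vim, an intermediate filament gene of reactive astrocytes, had 1113 ± 253 CPM (n = 4) in vehicle EAE against 113 ± 44.3 (n = 4), and C3, the central complement component, had 1499 ± 343 against 155 ± 57.3. Cyp51, an enzyme of cholesterol synthesis (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), had 39.9 ± 14.3 CPM against 166 ± 21.7, a log2 change of -1.81. In all, 576 genes were higher and 340 lower of 8428 tested by edgeR, 916 in all. Oligodendrocyte-like nuclei had 485 with all libraries, and this order turned to 482 against 1826 without vehicle EAE 4, 456 against 1180 without the mitochondria-rich libraries and 940 against 1403 with these as a term.

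The reactive astrocyte list had 19 of 20 members higher and 0 lower (20 adjusted over the list alone, median 2.76, adjusted p = 4.40e-35), with Serpina3n at 4.47 and Vim at 3.26. Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) had a ratio of 767, with a 95% exact binomial interval of 212 to 6345. Interferon-stimulated genes had 35 of 37 higher (37 adjusted over the list alone, median 3.104, adjusted p = 1.07e-38), MHC class I 16 of 19 (18 adjusted over the list alone, median 2.97, adjusted p = 2.49e-25) and MHC class II 5 of 5 (5 adjusted over the list alone, median 6.80, or 6.43 with genes at 0 counts at their bound, adjusted p = 2.35e-12). B2m, the MHC class I light chain, had 1342 ± 271 CPM against 66.0 ± 26.5, and H2-Ab1 was at least 86.5-fold higher. Complement had 9 of 10 higher (9 adjusted over the list alone, median 4.28, adjusted p = 1.64e-25), with Serping1 at 4.53 and C1qa at 4.79. The lipid export and LXR list had 6 of 11 higher (6 adjusted over the list alone, median 0.88, adjusted p = 3.81e-06), among them Apoe at 1.61 and the cholesterol exporter Abca1 at 1.56. Cholesterol synthesis had 16 of 21 lower and 0 higher (17 adjusted over the list alone, median -1.36, adjusted p = 6.85e-15). Of the astrocyte homeostasis list 6 of 17 fell and 0 rose (7 adjusted over the list alone, median -0.27, adjusted p = 0.000346, and 0.19 with an estimated correlation), including the glutamate receptor Gria2 at -1.24 and the phagocytic receptor Mertk at -1.23. NF-kB genes had 2 of 8 higher (2 higher and 1 lower adjusted over the list alone, median 0.39, adjusted p = 0.0212, 0.055 with an estimated correlation and 0.11 without vehicle EAE 4). Immediate early and heat shock genes had 5 of 13 higher (7 adjusted over the list alone, median 0.78, adjusted p = 0.000586, and 0.091 with an estimated correlation). Oxidative phosphorylation had 1 of 23 lower (adjusted p = 0.0393, and 0.52 with an estimated correlation). Proliferation (0.287) and glucocorticoid response (0.133) did not pass. The largest falls by the rule were Slco4a1, with a ratio of 0.0200 and an interval of 0.0005 to 0.115, Hsd11b1 (-3.09) and the hedgehog target Gli1 (-3.01).

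Immune transcripts of microglia and blood cells rose in astrocyte-like nuclei as well, 13 of 13 members with a median of 4.34 (13 adjusted over the list alone, adjusted p = 3.40e-37). Ribosomal protein genes had 6 of 29 higher (16 adjusted over the list alone, median 0.56, adjusted p = 1.03e-07, and 0.29 with an estimated correlation). Neuron transcripts had a median of -0.59 (adjusted p = 0.00601, and 0.38 with an estimated correlation), while oligodendrocyte (0.133) and mitochondrial transcripts (0.154) did not pass. Free RNA made up 35.6% in vehicle EAE and 50.9% in vehicle naive libraries, and after its subtraction 209 genes were higher and 197 lower. Within the libraries that are not mitochondria-rich 333 were higher and 123 lower, and without vehicle EAE 4, 350 and 132, with mitochondrial transcripts lower (adjusted p = 9.7e-05).

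In OPC-like nuclei 24 genes were higher and 2 lower of 2721 tested, led by interferon and MHC class I genes. H2-D1 rose by 3.38 on the log2 scale, B2m by 3.095 and H2-K1 by 3.25. Bst2, an interferon-induced membrane protein, had a ratio of 29.7 with a 95% exact binomial interval of 5.07 to 1199, and the interferon-induced Ifit3 and the leukocyte gene Cd52 each had a ratio of 15.3 with an interval of 5.02 to 75.9. The 2 lower genes were the bicarbonate transporter Slc4a4 (-1.44) and the neurofilament gene Nefl (-1.07). Only 4 interferon-stimulated genes passed the expression filter, and all 4 rose, also adjusted over the list alone (median 2.92, camera adjusted p = 1.10e-09). So did 3 of 6 MHC class I genes (4 adjusted over the list alone, median 2.15, adjusted p = 1.72e-09) and 2 of 7 disease-associated oligodendrocyte genes, C4b at 3.26 and Apod at 1.27 (3 adjusted over the list alone, adjusted p = 0.00132, and 0.21 after free RNA was subtracted). Oxidative phosphorylation had a median of -0.48 (2 of 20 lower adjusted over the list alone, adjusted p = 1.06e-08, and adjusted p = 0.086 with an estimated correlation). Cholesterol synthesis, glucocorticoid response and immediate early and heat shock genes had an adjusted p of 0.177 each. Immune transcripts rose in 9 of 10 members (10 adjusted over the list alone, median 3.28, adjusted p = 1.03e-17) and neuron transcripts fell (1 of 5, and 5 adjusted over the list alone, median -0.79, adjusted p = 7.35e-08). Mitochondrial (median -0.28, adjusted p = 0.00866) and ribosomal (median 0.25, adjusted p = 0.00134) transcripts each had an adjusted p of 0.40 with an estimated correlation, and oligodendrocyte transcripts did not pass (0.326). Free RNA made up 29.0% in vehicle EAE and 54.7% in vehicle naive libraries, and 3 genes were higher after its subtraction. When vehicle EAE 4 was left out the count was 28 higher and 36 lower, ribosomal proteins turned (0.86), and oligodendrocyte transcripts (0.0091) and immediate early and heat shock genes (0.042) were lower; without vehicle naive 4 the count was 43 in all.

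Microglia-like nuclei could be compared in only 2 vehicle naive libraries, of 24 and 30 nuclei, against 4 vehicle EAE libraries. Some genes of antigen presentation and of the disease-associated state rose, and no microglia list held its call with an estimated correlation, where the smallest adjusted p was 0.054. Apoe, a lipid carrier, had 24158 ± 5494 CPM (n = 4) in vehicle EAE against 2784 ± 1410 (n = 2), and Cd74 was at least 19.8-fold higher. In all, 46 genes were higher and 9 lower of 4542 tested. Disease-associated microglia genes had 5 of 23 higher (16 adjusted over the list alone, median 1.58, or 1.21 with genes at 0 counts at their bound, adjusted p = 4.24e-16), including Apoe at 3.11, the lysozyme gene Lyz2 at 2.75 and Cst7 with a ratio of 13.8 (95% exact binomial interval 2.44 to 546). Homeostatic microglia genes had 2 of 22 lower (2 adjusted over the list alone, median -0.51, adjusted p = 8.00e-06), Selplg at -1.81 and Cst3 at -1.48. The counts higher were 5 of 18 for MHC class I (10 adjusted over the list alone, adjusted p = 5.48e-08), 4 of 5 for MHC class II (4, adjusted p = 8.52e-05), 7 of 32 for interferon-stimulated genes (21, adjusted p = 3.12e-13), 2 of 19 for phagocytosis and lysosome (2, adjusted p = 1.23e-08), 1 of 13 for NF-kB (7, adjusted p = 0.00115) and 2 of 8 for lipid export and LXR (5 higher and 2 lower, adjusted p = 0.00143). The BTK, Fc receptor and antigen receptor list had 0 of 23 past the threshold and a median of 0.59 (adjusted p = 0.0260), and Btk itself had a log2 change of 0.63 (adjusted p = 0.739). Cholesterol synthesis (adjusted p = 0.0428) and oxidative phosphorylation (0.00335) were lower, and ribosomal proteins (1.64e-05) higher, while complement (0.213), proliferation (0.0818), glucocorticoid response (0.270), immediate early and heat shock (0.213), mitochondrial (0.408) and oligodendrocyte (0.156) transcripts did not pass and neuron transcripts were lower (0.00658). The largest falls by the rule were Il7r (-3.29), Csmd3 (-2.65) and Hdgfl3 (-2.44), and the other largest rises were Lgals3bp, at least 8.51-fold higher, and H2-Aa, at least 7.11-fold. Without vehicle naive 3 the count was 9 higher and 3 lower, and without vehicle naive 4 it was 9 and 1. With vehicle EAE 4 left out it was 105 in all, ribosomal proteins no longer passed (0.061), and mitochondrial (0.0083) and oligodendrocyte (0.0093) transcripts were lower.

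In neuron-like nuclei 42 genes were higher and 15 lower of 14885 tested. Interferon-stimulated genes rose and cholesterol synthesis genes fell. The former had 15 of 36 higher (32 adjusted over the list alone, median 1.49, adjusted p = 1.73e-41), with Ifit1 at 3.07. The latter had 8 of 24 lower and 0 higher (19 adjusted over the list alone, median -0.58, adjusted p = 1.18e-24), with Idi1 at -0.98 and Msmo1 at -0.96. MHC class I had 6 of 19 higher (11 adjusted over the list alone, median 1.16, adjusted p = 2.30e-16, and 0.81 after free RNA was subtracted). Oxidative phosphorylation had a median of -0.48 (9 of 23 lower adjusted over the list alone, adjusted p = 1.41e-16, and 0.092 with an estimated correlation), and immediate early and heat shock genes -0.31 (3 of 23 lower adjusted over the list alone, adjusted p = 0.000973, and 0.30 with an estimated correlation). Neuronal injury response (0.272), synaptic transmission (0.283), proliferation (0.108) and glucocorticoid response (0.109) did not pass. The largest rises by the rule were Cd74, with a ratio of 507 (95% exact binomial interval 90.7 to 20063), the chemokine Ccl5 (5.51) and Bst2 (4.37). Immune transcripts had 6 of 15 higher (12 adjusted over the list alone, median 2.91, adjusted p = 5.44e-13, and 0.092 with an estimated correlation), and 0.19 with the direction turned after free RNA was subtracted. Mitochondrial (median -0.51, adjusted p = 2.89e-06), ribosomal (-0.10, 0.0405) and oligodendrocyte (-0.41, 0.000205) transcripts had an adjusted p of 0.29, 0.65 and 0.31 with an estimated correlation. After subtraction of free RNA 2 genes were higher. The count was 95 higher and 97 lower with mitochondria-rich libraries as a term, 31 and 80 without them and 106 and 314 without vehicle EAE 4, where glucocorticoid response was lower (adjusted p = 0.011). The total was 22, 24, 23 and 24 without vehicle naive 1, 2 or 4 or vehicle EAE 3.

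**Figure D2:**
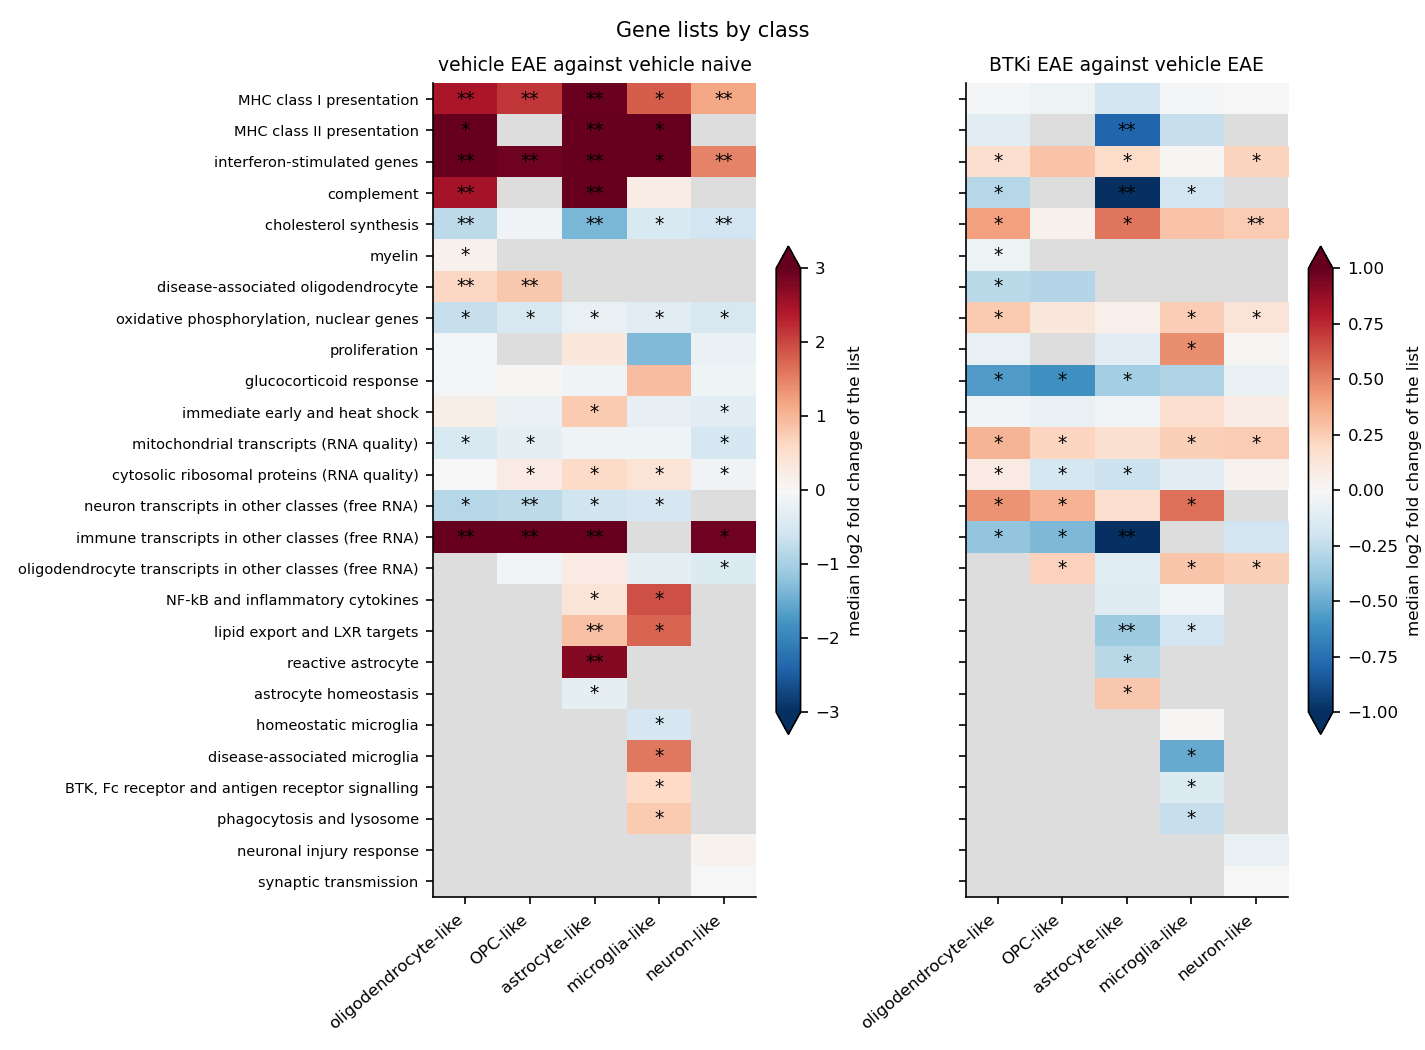
Median log2 change of each gene list (color scale) in 5 classes (columns), for vehicle EAE against vehicle naive and for BTKi EAE against vehicle EAE; 1 asterisk marks an adjusted p under 0.05 with the preset correlation, a pair of asterisks one that also holds with an estimated correlation, and grey a list not tested. Interferon-stimulated genes reach a median of 3.51 and cholesterol synthesis -0.78 in oligodendrocyte-like nuclei in disease.

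BTKi EAE was compared with vehicle EAE to show what the inhibitor changed in diseased mice. Astrocyte-like nuclei held the only genes past the threshold, and 14 of the 15 were lower. C1qc, a chain of complement C1q that microglia make (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065), had 126 ± 51.1 CPM (SD, n = 5) in BTKi EAE against 331 ± 85.1 (n = 4), a log2 change of -1.44 (edgeR adjusted p = 0.0007). Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944) had 15.5 ± 11.7 CPM against 66.8 ± 13.8, a log2 change of -2.19 (adjusted p = 0.0033). C1qb fell by 1.26, C1qa by 1.20 and the lysosomal protease gene Ctss by 0.97 on the log2 scale, and the RNA-binding protein gene Rbm4b rose by 1.09 (adjusted p = 0.0334). Other lower genes included Ctsd, Ctsz, Gpnmb, H2-Eb1, Lcp1, Ly86, Mob3b and Trem2; those of the 15 outside the naming rule were named after their values were seen. DESeq2 called 8, all lower.

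Complement in astrocyte-like nuclei had 3 of 10 members lower (C1qa, C1qb and C1qc, immune transcripts too) and 0 higher (6 adjusted over the list alone, median -1.07, camera adjusted p = 9.35e-18). MHC class II had 1 of 5 lower (5 adjusted over the list alone, median -0.79, adjusted p = 1.50e-08). Immune transcripts from other cells had 4 of 13 lower (13 adjusted over the list alone, median -1.06, adjusted p = 7.06e-36). The lipid export and LXR list had a median of -0.36 and 0 of 11 members past the threshold (adjusted p = 0.00161, and 0.17 without the mitochondria-rich libraries). These 4 lists are not independent and held with an estimated correlation. Cholesterol synthesis genes were higher in 20 of 21 members with a median of 0.54 and none past the threshold (adjusted p = 0.000232, and 0.18 with an estimated correlation). Cyp51 had a log2 change of 0.73 (adjusted p = 0.638). The reactive astrocyte list had a median of -0.28 (2 of 20 lower adjusted over the list alone, adjusted p = 2.69e-07, and 0.18 with an estimated correlation), where C3 had -0.75 (adjusted p = 0.336). Homeostasis genes had a median of 0.27 (adjusted p = 0.00161, 0.34 with an estimated correlation and 0.22 without vehicle EAE 4). Glucocorticoid response had -0.34 (7.63e-05, and 0.16 with an estimated correlation) and interferon-stimulated genes 0.18 (0.0231, and 0.61 with an estimated correlation). Ribosomal proteins had -0.22 (0.000232, 0.56 with an estimated correlation, and higher at 8.94e-08 after free RNA was subtracted). MHC class I (0.149), NF-kB (0.737), oxidative phosphorylation (0.253), proliferation (0.251), immediate early and heat shock (0.270), mitochondrial (0.0744), oligodendrocyte and neuron transcripts (0.434 each) did not pass. Free RNA made up 39.7% in BTKi EAE and 35.6% in vehicle EAE libraries. The count depends on libraries and settings: 0 genes passed without the mitochondria-rich libraries (357 at an unadjusted p under 0.05), 1 without vehicle EAE 4, 8 each without BTKi EAE 1, 3 or 5, 3 at a mitochondrial limit of 20%, and 1, which was higher, after subtraction of free RNA. Without vehicle EAE 4, oxidative phosphorylation (2.8e-06), mitochondrial (6.5e-08), neuron (0.0056) and oligodendrocyte (0.006) transcripts were higher, and ribosomal proteins turned to higher (0.048).

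In the other classes edgeR called 0 genes between BTKi EAE and vehicle EAE. At an unadjusted p under 0.05 there were 300 in oligodendrocyte-like, 84 in OPC-like, 128 in microglia-like, 214 in neuron-like and 39 in committed OPC-like nuclei, and DESeq2 also called 0 in each. Without vehicle EAE 4, 38 genes were higher and 2 lower in microglia-like nuclei. Lists did pass with the preset correlation. Cholesterol synthesis was higher in oligodendrocyte-like nuclei (24 of 24 members, median 0.41, 0 past the threshold and 2 adjusted over the list alone, adjusted p = 1.78e-13, and adjusted p = 0.11 with an estimated correlation) and in neuron-like nuclei (24 of 24, median 0.25, 0 and 4 adjusted over the list alone, adjusted p = 6.74e-18, and 0.037 with an estimated correlation), and did not pass in OPC-like (0.658) or microglia-like nuclei (0.354). In oligodendrocyte-like nuclei, glucocorticoid response (median -0.57, adjusted p = 1.75e-09), the disease-associated list (-0.27, 5.78e-05), complement (-0.28, 0.0135), myelin (-0.05, 0.0167) and immune transcripts (-0.40, 3.39e-07) were lower, and oxidative phosphorylation (0.26, 1.96e-08), mitochondrial (0.34, 1.13e-06), neuron (0.45, 8.23e-07) and ribosomal (0.08, 0.00645) transcripts and interferon-stimulated genes (0.16, 0.00724) were higher. None of these held with an estimated correlation, with adjusted p from 0.11 to 0.70. Without vehicle EAE 4 the disease-associated list (0.10) and the immune transcripts (0.33) no longer passed and complement turned (0.84); with mitochondria-rich libraries as a term myelin (0.22) and interferon-stimulated genes (0.064) did not pass and ribosomal proteins turned to lower (0.035). MHC class I (0.822), MHC class II (0.323), proliferation (0.624) and immediate early and heat shock genes (0.990) did not pass; MHC class II was lower with mitochondria-rich libraries as a term (adjusted p = 0.0013).

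In microglia-like nuclei, where BTK is expressed, Btk had 181 ± 63.2 CPM (n = 5) with the inhibitor and 194 ± 64.3 (n = 4) without, a log2 change of -0.09 (edgeR adjusted p = 0.999). In CPM of the summed counts Btk had 161 ± 58.5 in microglia-like and 174 ± 47.6 in monocyte/macrophage-like nuclei of vehicle EAE libraries, against at most 7.29 in the mean of any group of the other tested classes. Disease-associated microglia genes were lower with a median of -0.50 (0 of 23 past the threshold, 2 adjusted over the list alone, adjusted p = 4.90e-09, and adjusted p = 0.34 with an estimated correlation). Phagocytosis and lysosome (-0.23, 0.00917), complement (-0.19, 0.0332), lipid export and LXR (-0.19, 0.0332) and the BTK, Fc receptor and antigen receptor list (-0.14, 0.0332) were lower, and oxidative phosphorylation (0.24, 5.34e-05), mitochondrial (0.24, 0.000491), neuron (0.55, 6.44e-05) and oligodendrocyte (0.28, 0.0411) transcripts and proliferation (0.46, 3 members, 0.0437) were higher. None held with an estimated correlation, with adjusted p from 0.34 to 0.60. With mitochondria-rich libraries as a term the BTK list (0.69), oxidative phosphorylation (0.83) and mitochondrial transcripts (0.14) no longer passed, and without vehicle EAE 4 complement (0.095), phagocytosis and lysosome (0.095), lipid export and LXR (0.12) and proliferation (0.11) did not, while ribosomal proteins were higher (0.0074). MHC class I (0.963), MHC class II (0.268), interferon-stimulated genes (0.723), homeostatic microglia (0.765), NF-kB (0.532), glucocorticoid response (0.722), immediate early and heat shock (0.723) and ribosomal proteins (0.268) did not pass. Free RNA made up 41.0% in BTKi EAE and 35.0% in vehicle EAE libraries, and after its subtraction only the disease-associated list passed (0.00014).

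In OPC-like nuclei, glucocorticoid response (median -0.62, adjusted p = 0.000245), ribosomal proteins (-0.18, 0.00587) and immune transcripts (-0.45, 0.000577) were lower and mitochondrial (0.22, 0.00211), oligodendrocyte (0.23, 0.00641) and neuron (0.34, 0.000245) transcripts higher, none with an estimated correlation, where adjusted p ran from 0.16 to 0.62. Without vehicle EAE 4, glucocorticoid response (0.10) and immune transcripts (0.71) did not pass, ribosomal proteins turned (0.13) and oxidative phosphorylation was higher (1.3e-05). MHC class I (0.990), interferon-stimulated genes (0.0832), the disease-associated list (0.0536), oxidative phosphorylation (0.147) and immediate early and heat shock genes (0.658) did not pass. In neuron-like nuclei, interferon-stimulated genes were higher (0.23, 1.11e-08, and adjusted p = 0.093 with an estimated correlation), as were oxidative phosphorylation (0.13, 0.00128), mitochondrial (0.25, 0.00128) and oligodendrocyte (0.23, 0.0052) transcripts, each with an adjusted p of 0.85 with an estimated correlation and turned in direction, without passing, with mitochondria-rich libraries as a term (0.97, 0.97 and 0.53). MHC class I (0.968), neuronal injury response (0.302), synaptic transmission (0.713), proliferation (0.795), glucocorticoid response (0.381), immediate early and heat shock (0.264), ribosomal proteins (0.210) and immune transcripts (0.0557) did not pass. Without vehicle EAE 4, ribosomal proteins (9.5e-14), immediate early and heat shock genes (0.0035) and MHC class I (0.025) were higher; with mitochondria-rich libraries as a term MHC class I (0.0035) and ribosomal proteins (0.0029) were lower.

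**Figure D3:**
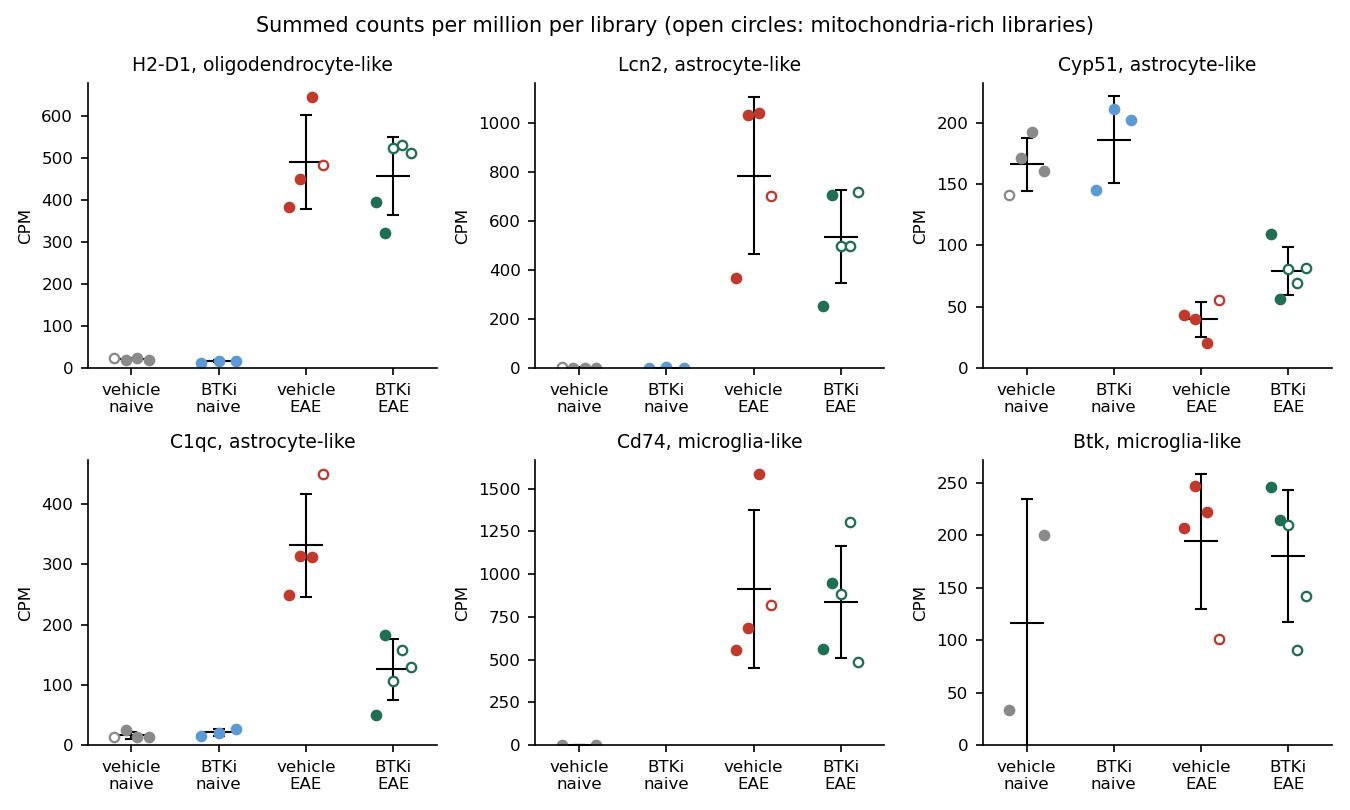
CPM (vertical axes) of 6 genes in each library, by group, with the group mean and SD as a black bar and mitochondria-rich libraries as open circles. C1qc in astrocyte-like nuclei averages 331 CPM in vehicle EAE and 126 CPM in BTKi EAE libraries, and Btk in microglia-like nuclei 194 and 181.

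BTKi naive was compared with vehicle naive to show what the inhibitor changed without disease. No gene passed in any class, and 7 list tests passed with the preset correlation. edgeR called 0 genes in oligodendrocyte-like (354 at an unadjusted p under 0.05), OPC-like (81), astrocyte-like (300) and neuron-like nuclei (549), and DESeq2 called 0 as well. With the library number as a block over all groups the fit again called 0, with 368, 79, 326 and 772 at an unadjusted p under 0.05. Cholesterol synthesis (median -0.24) and the reactive astrocyte list (-0.48, 1 of 20 lower adjusted over the list alone) were lower in astrocyte-like nuclei, as were neuron transcripts (-0.23), each with an adjusted p of 0.00539, and at least 0.91 with an estimated correlation. In oligodendrocyte-like nuclei interferon-stimulated genes were higher (0.18, 0.0367) and myelin (-0.15, 0.0224) and immediate early and heat shock genes (-0.35, 0.0224) lower, and the last list was lower in neuron-like nuclei too (-0.22, 0.0163). None of these held with an estimated correlation either. With that block, which the EAE libraries share, these 7 calls stayed, and others passed: ribosomal proteins were higher in oligodendrocyte-like (camera adjusted p = 0.0013), astrocyte-like (0.0025) and neuron-like nuclei (1.4e-05), oligodendrocyte transcripts in astrocyte-like (0.0038) and neuron-like nuclei (0.025), mitochondrial transcripts in astrocyte-like nuclei (0.015) and glucocorticoid response in OPC-like nuclei (0.025), and synaptic transmission was lower in neuron-like nuclei (0.025). Microglia-like nuclei were too few in naive libraries for this comparison and for the interaction.

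The interaction asked whether the inhibitor's change differed between EAE and naive mice. No single gene passed: edgeR called 0 in oligodendrocyte-like (327 at an unadjusted p under 0.05), OPC-like (85), astrocyte-like (266) and neuron-like nuclei (364), and DESeq2 called 0. Cholesterol synthesis changed more towards higher values in EAE than in naive mice in oligodendrocyte-like (median 0.45, camera adjusted p = 2.73e-08), astrocyte-like (0.71, 1.88e-07) and neuron-like nuclei (0.43, 2.45e-12), with adjusted p of 0.62, 0.15 and 0.12 with an estimated correlation. Immune transcripts in astrocyte-like nuclei went the other way (-0.96, 1.17e-10, and adjusted p = 0.15 with an estimated correlation).

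Across genes, the changes with disease and with treatment in EAE ran in opposite directions, and the vehicle EAE libraries that both share produce a negative correlation without any effect. Pearson's r across genes was -0.46 in oligodendrocyte-like, -0.37 in OPC-like, -0.54 in astrocyte-like, -0.21 in microglia-like and -0.35 in neuron-like nuclei, and genes are not independent replicates. Simulations with no effect gave -0.49, -0.45, -0.58, -0.17 and -0.51. With different vehicle EAE libraries on each side, r was -0.13, 0.0076, -0.19, -0.043 and 0.050. In all 6 such partings it stayed negative in astrocyte-like (-0.28 to -0.087) and oligodendrocyte-like nuclei (-0.23 to -0.033), and it took both signs in the other 3 classes. The covariance differed from the simulated one by -0.095 in astrocyte-like, -0.033 in oligodendrocyte-like, -0.029 in microglia-like, -0.0080 in OPC-like and 0.0005 in neuron-like nuclei. These were -0.061, -0.10, -0.15, -0.038 and -0.013 without vehicle EAE 4.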

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

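The 3 patterns below and the grouping by mitochondrial RNA were chosen after the results were seen; each prediction was then written before its test was run, except that of free RNA for the cholesterol synthesis genes, which was written after.

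The first pattern is that microglial transcripts rose in astrocyte-like nuclei in EAE and were lower there with the BTK inhibitor. If free RNA alone brought them, their level relative to the shallowest barcodes would equal the free-RNA share read from neuron transcripts; it was 2.12, 2.35, 2.91 and 1.33 times that share in vehicle EAE 1 to 4, and the lowest, 1.3303, lies within the 1.5 times set in advance. If astrocyte and microglial nuclei shared droplets, C1q genes and fixed microglia markers would imply like shares; the ratio of these shares was 2.22, 1.96, 2.53 and 1.67, and the lowest, 1.6733, lies within the 2 times set in advance. Both explanations therefore stay open, and both may act together with expression by astrocytes in the disease group, which was not tested apart from them, and the shared vehicle EAE libraries by themselves favour opposite moves in the 2 comparisons. Immune transcripts in the shallowest 25% of barcodes averaged 15183 CPM in vehicle EAE and 9458.7 in BTKi EAE libraries, against 3369.7 in the highest naive library. Single libraries overlapped (BTKi EAE up to 14266, vehicle EAE from 13043 CPM), no test was run on these means, and shallow immune nuclei would raise them as free RNA does.

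The second pattern is that cholesterol synthesis genes were lower in EAE and higher with the BTK inhibitor in oligodendrocyte-like, astrocyte-like and neuron-like nuclei. Free RNA as the whole cause would leave at most 1 of the 6 list calls after its subtraction, and 6 of 6 stayed in direction and past the threshold with the preset correlation. A shift in cytoplasmic RNA shared with the oxidative phosphorylation genes would do the same with that list as a term, and 6 of 6 stayed. The 2 comparisons share the vehicle EAE libraries, so the 6 calls are not independent and opposite moves arise with no effect (r of -0.49, -0.58 and -0.51 across all genes in simulations of these classes); what this gives for the list was not tested. That, a difference in sterol synthesis and a change in the make-up of each class all stay open, and with an estimated correlation the treatment call held in neuron-like nuclei alone.

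The third pattern is that vehicle EAE 4 stood apart in oligodendrocyte-like nuclei, where the disease comparison called 485 genes with it and 1826 without it. Among nuclei with at least 1000 genes the count without it was still 3.884 times the count with it, which argues against shallow nuclei as the cause. After free RNA was subtracted in every library the count without it was 0.7217 times the count with it (83 against 115), so free RNA in that library is a candidate source of the difference. Vehicle EAE 4 held 36029 barcodes against 7410 in the nearest other vehicle EAE library, and 52.6% of its barcodes past the UMI and gene minima failed the mitochondrial limit against 9.79%. No biological explanation was tested, since the labels put it in no group of its own.

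The split of the libraries into vehicle EAE and vehicle naive was set beside all 35 splits of the same 8 libraries. The share of splits set in advance as the limit for chance was 0.05. In OPC-like nuclei 1 of 35 splits gave at least the real 26 genes, which is under that limit. The highest other, which set vehicle EAE 4 with vehicle naive 1, 2 and 4, gave 25, close to the real count. In astrocyte-like nuclei 1 of 35 gave at least 916, also under the limit, and the highest other gave 42, far below it. A share of 1 of 35 is the smallest these splits can give and was not adjusted over classes. With 25 beside 26 it does not exclude chance in OPC-like nuclei. For the count of genes alone chance is also not excluded in oligodendrocyte-like nuclei, where 2 of 35 gave at least 485 and the highest other, 607, set vehicle EAE 4 with vehicle naive 1, 2 and 3, nor in neuron-like nuclei, where 2 of 35 gave at least 57 and the highest other, 631, set it with vehicle naive 1, 2 and 4. These splits of oligodendrocyte-like and neuron-like nuclei both put the mitochondria-rich vehicle EAE 4 and vehicle naive 1 on the same side, and likewise vehicle naive 1 and 2 and vehicle EAE 4, the libraries of these groups over 30000 barcodes, which points to a structure of the samples that either grouping follows. With mitochondria-rich libraries as a term the real counts were 1403 and 192, and without the libraries over 30000 barcodes 813 and 34. These counts leave aside the lists fixed in advance, of which interferon-stimulated genes had an adjusted p of 0.00108 in oligodendrocyte-like and 0.000369 in neuron-like nuclei with an estimated correlation. In microglia-like nuclei 2 vehicle naive libraries leave too few splits for such a share under 0.05.

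For BTKi EAE against vehicle EAE, 3 of 100 drawn splits gave at least the 15 genes of astrocyte-like nuclei. Unadjusted over classes and with 29 in another split, this does not exclude chance. In the other classes the real count was 0, which all 100 splits reach by construction, so they decide nothing. The highest split gave 29 genes in OPC-like, 204 in committed OPC-like, 423 in microglia-like, 449 in neuron-like and 1387 in oligodendrocyte-like nuclei. In the last 4 classes this split set BTKi EAE 1 and 2 with vehicle EAE 1, 2 and 3 against vehicle EAE 4 with BTKi EAE 3, 4 and 5, exactly the mitochondria-rich libraries, which points to a structure of the samples that follows this grouping. Without those libraries the real counts were 0 in oligodendrocyte-like, neuron-like and microglia-like nuclei and 1 in committed OPC-like nuclei. For BTKi naive against vehicle naive all 35 of 35 splits reach the real 0, which decides nothing either, with 2, 21, 142 and 41 as the highest others in OPC-like, astrocyte-like, neuron-like and oligodendrocyte-like nuclei. For the interaction all 100 of 100 reach it, with 23, 53, 410 and 837.

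Single libraries stood far from the rest of their group in 23 of 116 comparisons, by a gap to the nearest library over the range above Dixon's 95% value, where chance alone gives about 1 in 20 groups. That rate does not hold where the other libraries are all at 0, since any count then passes; this is so wherever the nearest other value below is 0. In BTKi EAE 5, T/NK-like nuclei made up 1.21% of named nuclei (nearest other library 0.342%), endothelial-like 1.495% (0.542%), microglia-like 8.60% (3.82%) and neuron-like 34.3% (47.6%). In BTKi EAE 2, monocyte/macrophage-like nuclei made up 2.42% (0.822%). Fibroblast-like nuclei made up 0.547% in vehicle naive 1 (0.0545%), and monocyte/macrophage-like nuclei 0.0545% in vehicle naive 3 (0), as did the peripheral immune classes together. BTKi EAE 4 held 42812 barcodes (9016) and 37892000 UMIs to 5 digits (13903000).

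Named genes stood apart in single libraries as well. In vehicle naive 4, Cd74 had 0.752 CPM in oligodendrocyte-like nuclei (nearest other 0) and Bst2 and Ifit3 had 10.2 and 30.5 CPM in OPC-like nuclei (0 and 0). In OPC-like nuclei Cd52 had 320.1 CPM in vehicle EAE 4 (139) and Slc4a4 461 CPM in vehicle naive 2 (173). In astrocyte-like nuclei Lcn2 had 3.75 CPM in vehicle naive 1 (0), Slco4a1 4.36 CPM in vehicle EAE 1 (0) and Hsd11b1 0 CPM in vehicle EAE 3 (12.3). In neuron-like nuclei Cd74 had 0.322 CPM in vehicle naive 1 (0), and Bst2 39.8 CPM (12.9) and Idi1 41.8 CPM (28.7) in vehicle EAE 4.

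The inhibitor's change differed between EAE and naive mice for 22 lists by the interaction test with the preset correlation, and for none with an estimated correlation. Several, such as oxidative phosphorylation, mitochondrial and neuron transcripts in oligodendrocyte-like nuclei, turned in direction with mitochondria-rich libraries as a term or with free RNA subtracted (values under the alternatives). In oligodendrocyte-like nuclei cholesterol synthesis (camera adjusted p = 2.73e-08), oxidative phosphorylation (6.82e-05), immediate early and heat shock (0.0294), mitochondrial (0.00913) and neuron (0.000246) transcripts changed towards higher values in EAE, and glucocorticoid response (5.24e-05) and immune transcripts (0.0242) towards lower. In OPC-like nuclei glucocorticoid response (0.000511) went lower and neuron transcripts (0.00331) higher. In astrocyte-like nuclei cholesterol synthesis (1.88e-07), homeostasis (0.0351) and neuron transcripts (0.0146) went higher, and MHC class II (0.0351), complement (0.000618), glucocorticoid response (0.00342), ribosomal proteins (0.000475), oligodendrocyte (0.0407) and immune (1.17e-10) transcripts lower. In neuron-like nuclei interferon-stimulated genes (0.0297), cholesterol synthesis (2.45e-12), oxidative phosphorylation (0.0184) and immediate early and heat shock genes (0.00405) went higher.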

How the results depend on the processing

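The tests chosen after the data were seen are those with a mitochondrial limit of 20%, free RNA subtracted, at least 10 nuclei per library, unnamed clusters counted, the cholinergic cluster left out of the main neuron-like class, mitochondria-rich libraries as a term or left out, and, for lists and correlations, vehicle EAE 4 left out. No class share passed the threshold under any alternative (351 comparisons, and 312 with a library left out), which says nothing about stability where 4 libraries face 4 or 3, since even full separation there gave an adjusted p of 0.0619 in disease. Of alternatives to gene counts 259 stayed within 1.5 times and 46 did not, to list counts 78 and 48, to correlations 6 and 9. Most main gene counts were 0, so most of the 259 stayed 0. Median-ratio size factors, Leiden resolution 0.5, at least 10 nuclei per library, doublets kept and no barcode limit moved no gene count by over 1.5 times. The cause of differences below was not tested, except that fewer libraries or genes lower power by construction. The microglia-like disease comparison rests on 2 vehicle naive libraries of 24 and 30 nuclei and recovered 1.49% of simulated 2-fold changes. Same-numbered libraries of vehicle EAE and vehicle naive correlated from -0.167 to 0.030 in astrocyte-like, -0.022 to 0.146 in neuron-like and -0.264 to 0.090 in oligodendrocyte-like nuclei, and those of vehicle EAE and BTKi EAE from 0.014 to 0.092, 0.034 to 0.417 and -0.0083 to 0.332. Not every pair passed 0.1 and not every library correlated best with its own number, so these were not taken as pairs; same-numbered libraries also share a library set. The replicate block moved the counts given below, and no other count by over 1.5 times.

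Counts of genes in disease moved as follows (oligodendrocyte-like 485, OPC-like 26, astrocyte-like 916, microglia-like 55, neuron-like 57). With free RNA subtracted they were 115, 3, 406 and, in neuron-like nuclei, 2. With no filter on low counts they were 1244 in oligodendrocyte-like, 60 in OPC-like, 99 in microglia-like and 112 in neuron-like nuclei. Without the 5 libraries over 30000 barcodes they were 813, 14, 433, 100 and 34, and without the mitochondria-rich libraries 1180 in oligodendrocyte-like, 456 in astrocyte-like, 107 in microglia-like and 111 in neuron-like nuclei. With mitochondria-rich libraries as a term they were 1403 in oligodendrocyte-like and 192 in neuron-like nuclei. With at least 1000 genes per nucleus they were 294 in oligodendrocyte-like and 498 in astrocyte-like nuclei. DESeq2 gave 31 in microglia-like and 184 in neuron-like nuclei, the replicate block 83 and 213, unnamed clusters counted 83 and 159, and the library set as a term 136 in neuron-like nuclei. Unnamed clusters counted as neuron-like include the one led by Tyrobp, C1qb and Fcer1g, with 1297 vehicle EAE and 76 vehicle naive nuclei.

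The 15 genes of astrocyte-like nuclei in BTKi EAE against vehicle EAE became 8 with DESeq2, 8 with at least 1000 genes, 1 with free RNA subtracted, 3 with a mitochondrial limit of 20%, 30 with no filter, 6 with the block, 2 without the libraries over 30000 barcodes and 0 without the mitochondria-rich ones. Counts of 0 in this comparison became 1 in OPC-like, 1 in microglia-like and 22 in oligodendrocyte-like nuclei with no filter, 1 in neuron-like nuclei with the block, 13 in microglia-like nuclei without the libraries over 30000 barcodes, and 1 in committed OPC-like nuclei without the mitochondria-rich ones. In the naive comparison 1 gene passed in oligodendrocyte-like nuclei with no filter and 1 in astrocyte-like nuclei without the libraries over 30000 barcodes, and in the interaction 3 in oligodendrocyte-like and 1 in astrocyte-like nuclei with no filter.

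With each library left out in turn, disease counts ran from 280 to 1826 in oligodendrocyte-like, 21 to 64 in OPC-like, 482 to 915 in astrocyte-like, 10 to 105 in microglia-like and 22 to 420 in neuron-like nuclei. The treatment counts ran from 1 to 22 in astrocyte-like, 0 to 40 in microglia-like and 0 to 1 in oligodendrocyte-like nuclei, the last without BTKi EAE 2, and stayed at 0 elsewhere. All naive and interaction counts stayed at 0. The highest counts in oligodendrocyte-like, OPC-like, neuron-like and microglia-like nuclei were those without vehicle EAE 4. Other counts moved by over 1.5 times in disease without vehicle naive 1 or 2 or vehicle EAE 2 or 3 in oligodendrocyte-like, vehicle naive 4 in OPC-like, vehicle EAE 4 in astrocyte-like, vehicle naive 3 or 4 in microglia-like and vehicle naive 1, 2 or 4 or vehicle EAE 3 in neuron-like nuclei, and in treatment without vehicle EAE 4 or BTKi EAE 1, 3 or 5 in astrocyte-like nuclei. Without it the lists past the threshold were 8 in place of 5 for treatment in neuron-like nuclei, and for the interaction 5 in place of 2 in OPC-like, 5 in place of 9 in astrocyte-like and 7 in place of 4 in neuron-like nuclei. Without it disease and treatment changes correlated at -0.62 in oligodendrocyte-like, -0.52 in OPC-like, -0.37 in microglia-like and -0.47 in neuron-like nuclei, against -0.46, -0.37, -0.21 and -0.35; simulations with no effect gave -0.580, -0.531, -0.218 and -0.573 without it, so part of the shift comes from the shared libraries.

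Lists past the threshold with an estimated correlation were 6 of 11 for disease and 0 of 11 for treatment, 0 of 3 for naive and 0 of 7 for the interaction in oligodendrocyte-like nuclei; 5 of 8, 0 of 6 and 0 of 2 (interaction) in OPC-like; 8 of 14, 4 of 10, 0 of 3 and 0 of 9 in astrocyte-like; 0 of 13 and 0 of 10 in microglia-like; and 3 of 9, 1 of 5, 0 of 1 and 0 of 4 in neuron-like nuclei. With free RNA subtracted they were 4, 4, 1 and 2 in oligodendrocyte-like, 2, 2 and 0 (interaction) in OPC-like, 1 for naive and 1 for the interaction in astrocyte-like, 6 and 1 in microglia-like, and 4, 2 and 0 for naive in neuron-like nuclei. With the library set as a term they were 5 for naive in astrocyte-like and 1 for the interaction in neuron-like nuclei, and with mitochondria-rich libraries as a term 6, 5 and 4 for naive in oligodendrocyte-like, astrocyte-like and neuron-like nuclei. With the block they were 1, 6 and 4 for naive in OPC-like, astrocyte-like and neuron-like nuclei and 4 for the interaction in OPC-like nuclei, which also had 4 without the libraries over 30000 barcodes. Without the mitochondria-rich libraries they were 1 for naive and 4 for the interaction in oligodendrocyte-like, 3 for treatment and 1 for the interaction in OPC-like, 4 for the interaction in astrocyte-like, and 5 for naive and 2 for the interaction in neuron-like nuclei. The correlation was -0.13, 0.0076, -0.19, -0.043 and 0.050 in the 5 classes with different vehicle EAE libraries on each side, -0.38 in microglia-like nuclei without the libraries over 30000 barcodes, and -0.34, -0.40 and -0.21 in oligodendrocyte-like, astrocyte-like and neuron-like nuclei without the mitochondria-rich ones.

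List directions turned after free RNA was subtracted, with these adjusted p. In disease they were mitochondrial 0.990 and neuron transcripts 0.990 in oligodendrocyte-like, oxidative phosphorylation 0.604, mitochondrial 0.4661 and neuron 0.555 in OPC-like, oxidative phosphorylation 0.831, ribosomal 0.984 and neuron 0.831 in astrocyte-like, ribosomal 0.174 in microglia-like, and mitochondrial 0.551, ribosomal 0.858 and immune 0.191 in neuron-like nuclei. In treatment they were complement 0.910 and mitochondrial 0.910 in oligodendrocyte-like, mitochondrial 0.759, oligodendrocyte 0.329 and neuron 0.673 in OPC-like, ribosomal 8.94e-08 in astrocyte-like, mitochondrial 0.594 and oligodendrocyte 0.608 in microglia-like, and mitochondrial 0.969 in neuron-like nuclei. In the interaction they were mitochondrial 0.898, neuron 0.898 and immune 0.994 in oligodendrocyte-like, neuron 0.639 in OPC-like, and ribosomal 0.674 and neuron 0.968 in astrocyte-like nuclei. Ndufa4 in astrocyte-like and H2-D1 in neuron-like nuclei turned to log2 changes of 1.39 and -0.067 in disease.

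With mitochondria-rich libraries as a term, directions turned in treatment for ribosomal proteins (0.0352) in oligodendrocyte-like, oligodendrocyte transcripts (0.874) in microglia-like, and MHC class I (0.00345), oxidative phosphorylation (0.967), mitochondrial (0.971), ribosomal (0.00285) and oligodendrocyte (0.529) transcripts in neuron-like nuclei. In the naive comparison oxidative phosphorylation turned in oligodendrocyte-like nuclei (0.00642). In the interaction oxidative phosphorylation (0.413), mitochondrial (0.540) and ribosomal (1.25e-05) transcripts turned in oligodendrocyte-like, mitochondrial (0.0323) in astrocyte-like, and oxidative phosphorylation (0.240), mitochondrial (0.0291) and oligodendrocyte (0.000707) in neuron-like nuclei.

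Without the libraries over 30000 barcodes ribosomal proteins turned in OPC-like nuclei in disease (0.482) and treatment (0.930), in astrocyte-like nuclei in treatment (0.258) and the interaction (0.303) and in neuron-like nuclei in the interaction (0.01003), and oligodendrocyte transcripts in astrocyte-like nuclei in treatment (0.0237) and the interaction (0.822). Omission of vehicle EAE 4 turned the same results, with 0.860, 0.131, 0.0475, 0.589, 0.000223, 0.00596 and 0.573 in that order, and complement in oligodendrocyte-like (0.840) and ribosomal proteins in microglia-like nuclei (0.00735) in treatment. Without the mitochondria-rich libraries ribosomal proteins in OPC-like nuclei turned in disease (0.966). Of single named genes, 178 results weakened and 111 passed under another setting, and 151 weakened and 46 passed with a library left out.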

Other observations

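The rule that names the classes was set after their markers were seen, and no test in this part was chosen after its result was seen.

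Committed OPC-like nuclei reached 20 per library in EAE alone, with 246 nuclei in vehicle EAE and 242 in BTKi EAE, so their disease change could not be tested. Between those groups edgeR called 0 of 2291 genes, with 39 at an unadjusted p under 0.05 and 0 by DESeq2. Monocyte/macrophage-like nuclei numbered 275 in vehicle EAE and 126 in BTKi EAE, T/NK-like nuclei 74 and 35, and dendritic-like nuclei 75 and 39. Endothelial-like nuclei, which line vessels, numbered 64, 37, 48 and 58 in vehicle naive, BTKi naive, vehicle EAE and BTKi EAE; of these 0, 0, 24 and 12 lay in a cluster whose leading genes also hold S100a8 and S100a9 of neutrophils. In the same order mural-like nuclei, which wrap vessels, numbered 83, 26, 49 and 48.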
